A study of Mus musculus with 10 samples.

How the data were processed

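The deposited table held read counts per Ensembl gene for 10 tumors, 5 per group, and its values were whole numbers that were not scaled between samples. Per the submitters' processing notes, the tools fastp, HISAT, Bowtie and RSEM and the genome build mm10 were used. Their roles, order and versions, the annotation release, the counting rule and the use of strand are not given in the sources used here. RSEM gives estimated counts, so the deposited counts can be rounded estimates, and reads of near-identical genes can be split between them. The table listed 17737 genes, of which 40 had 0 counts in all samples. Symbols were matched for 17670 identifiers and not for 67. Coordinates came from GENCODE mouse release 21 on the same build.

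Each column was assigned to a tumor by its name, and no column remained unassigned. Total counts per tumor ranged from 25904345 to 37578722, so 3 counts, taken as a floor, came to between 0.08 and 0.116 CPM. Intervals and floors from counts cover counting error only. No 2 tumors of a group agreed within sampling noise, with a smallest chi-square per degree of freedom of 13.9 over genes with at least 20 counts in the pair, unlike 1 library sequenced again. This does not tell whether 2 samples came from 1 mouse. Each sample was treated as 1 replicate.

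Genes with low counts were removed with edgeR's filterByExpr by group, library sizes were scaled by TMM, and D69A was compared with WT by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with Benjamini-Hochberg adjustment over 13798 genes and a threshold of 0.05. SEs of log2 fold changes were derived from the F statistic. CPM were computed with the TMM factors. Before the data were examined, 26 gene lists for pathways and cell types were fixed and each was tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, requiring 5 tested members. Each list also received a per-tumor score, the mean log2 CPM of its members, compared by a two-sided exact permutation test over 252 assignments with a smallest p of 0.00794. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were alternatives.

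The genes named were chosen by a rule fixed before the data were examined: Il18, the 12 largest increases and 12 largest decreases past the threshold with a mean of at least 1 CPM and a symbol other than a clone, receptor segment or pseudogene name, and up to 4 members of each list with the smallest p. From these the text takes a part. Kit, Lamp1, Fbln1, Pdia3, Gzmc, Gzmd, Sqle, Fasn, Scd1, C3, C4b and Serping1 lie outside the rule and were chosen after their values were seen.

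The test was checked on simulated counts for 13798 genes with the real means and library sizes, 200 of them changed. It recovered 6% of the genes at the smallest simulated change, which was below 1.5-fold, 52% at 1.5-fold, 74% at 2-fold and 100% at 4-fold, and 3.33% of its calls were unchanged genes. The simulated genes were independent of each other, so the simulation does not test list calls under correlation between genes. Far fewer genes were changed than passed in the real data, so the recovered shares do not carry over to it.

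Alternatives fixed before the data were examined were DESeq2 (version 1.42.0), limma-voom with and without sample weights, RLE and upper quartile scaling, library size only, removal of Il18, other filters, a test against a fold of 1.5, an adjusted p of 0.01, the replicate number as a block, and leaving out each tumor. An analysis without the 3 tumors highest in skeletal muscle markers was added after the data were seen.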

Results

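Bulk RNA was sequenced from tumors grown under the skin of C57BL/6 mice from B16-F10 cells, a mouse melanoma line. The implanted cells overexpressed either wild-type IL-18 (WT tumors) or an IL-18 in which the aspartate at position 69 was replaced by alanine (D69A tumors). IL-18 is a cytokine of the IL-1 family that is made as an inactive precursor, is released in active form after cleavage by caspases, and drives interferon-gamma production by natural killer (NK) and T cells. Each group held 5 tumors, all collected on day 11. Total counts lay between 25904345 and 37556163 in WT tumors and between 34400949 and 37578722 in D69A tumors. The lowest total belonged to WT tumor 6. A tumor of either kind holds melanoma cells and host cells, so each value below is a level in the whole tissue. The labels describe the tumors as separate samples and do not state whether each came from its own mouse, so the p-values measure the spread between these samples.

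The level of the overexpressed gene was not detectably different between the groups. Il18 (chromosome 9, 50554827 to 50581840 in mm10) stood at 29.6 ± 2.56 CPM (counts scaled to library size) in WT tumors and at 27.3 ± 2.41 CPM in D69A tumors (SD, n = 5 each). The log2 fold change of D69A against WT was -0.12 with an SE of 0.08, which did not pass the threshold (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.266). Gene counts do not separate the introduced from the endogenous transcript or the WT from the mutant sequence, so this level does not check which form a tumor carried. By mean CPM Il18 ranked 7030 among the tested genes, with 49.1% of them lower. No tumor without overexpression was analysed here, so the size of the overexpression was not measured.

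The comparison of D69A with WT tumors asks how the transcriptome of the tumor differs when the introduced IL-18 carries the substitution. D69A tumors had far lower transcript levels of immune and stromal genes, among them interferon response, NK cell and T cell genes, and slightly higher levels of pigment cell genes. Of 13798 genes tested, 6004 (43.5%) passed the threshold, with 2594 higher and 3410 lower in D69A tumors. The large changes were nearly all decreases. Among genes past the threshold, 2180 were lower and 70 higher by at least 2-fold, and 1107 were lower and 8 higher by at least 4-fold. The first principal component held 70.8% of the variance and placed all WT tumors (-82.5 to -18.0) below all D69A tumors (5.2 to 74.7), with WT tumor 2 and D69A tumor 1 nearest to each other.

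**Figure D1:**
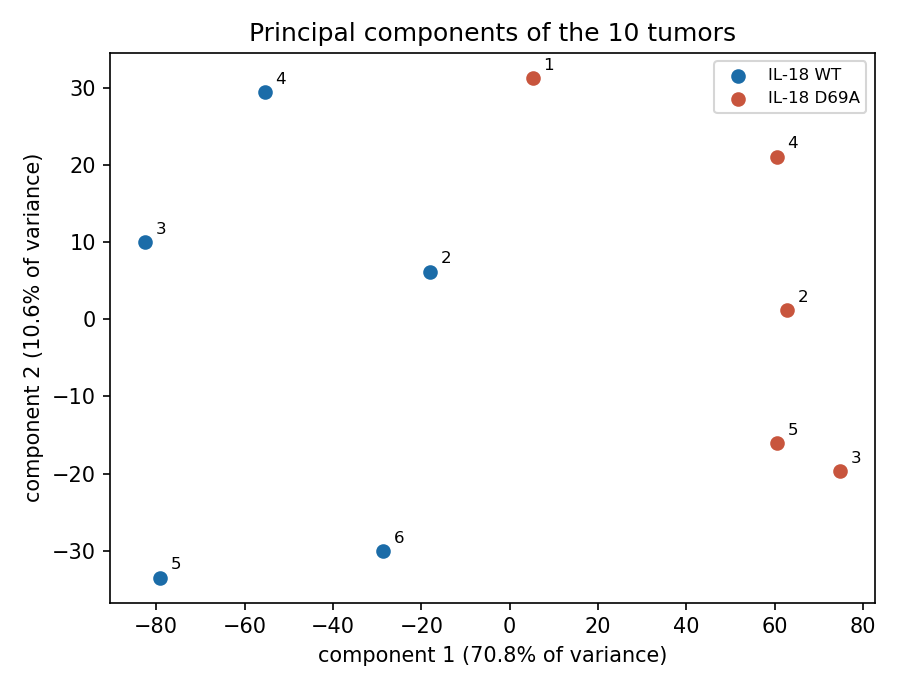
Principal components of log2 CPM over the tested genes; each point is a tumor with its replicate number, blue for WT and red for D69A. The first component (70.8% of variance) separates the groups, with WT tumor 2 at -18.0 and D69A tumor 1 at 5.2.

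Interferon response genes fell together. All 36 tested members of the type I interferon list were lower in D69A tumors, over all genes and when adjusted over the list alone (36), with a median log2 fold change of -2.37. All 32 tested members of the interferon-gamma list were lower by both counts (32 adjusted over the list alone), with a median of -2.28. Rsad2, which encodes the antiviral protein viperin, stood at 224.7 ± 41.2 CPM in WT and 63.9 ± 11.7 CPM in D69A tumors (SD, n = 5 each; log2 fold change -1.81, SE 0.15). Ifit3 was 7.8-fold lower, although reads can be shared with its near-identical neighbor Ifit3b, and Ifit1 was 5.92-fold lower. Irf1, a transcription factor induced by interferon-gamma, was 3.31-fold lower, the GTPase gene Irgm1 3.33-fold lower and the feedback inhibitor gene Socs1 4.78-fold lower. The per-tumor score, which is the mean log2 CPM of the members, was 6.65 ± 0.34 in WT against 4.31 ± 0.50 in D69A tumors for the type I list (SD, n = 5 each) and 6.30 ± 0.45 against 4.00 ± 0.57 for the interferon-gamma list. Both differences gave p = 0.00794 in a two-sided exact permutation test, the smallest p that 5 against 5 tumors allow (adjusted p = 0.0115 over 26 lists). Limma's camera with a preset correlation called both lists, and neither call held with an estimated correlation (adjusted p = 0.213 for both).

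Lymphocyte and cytotoxicity genes were lower in D69A tumors. All 25 tested NK cell markers and all 24 tested T cell markers were lower in D69A tumors, with the same counts (25 and 24) adjusted over the list alone and medians of -2.74 and -2.65. Klrb1c, which encodes the NK receptor NK1.1, was 7.38-fold lower, the cytokine receptor gene Il2rb 6.64-fold lower and the chemokine gene Xcl1 8.17-fold lower. The T cell kinase gene Lck was 3.51-fold lower and Foxp3, the defining transcription factor of regulatory T cells, 7.11-fold lower. All 10 tested members of the T cell inhibitory receptor list were lower (10 adjusted over the list alone), although its members Tox and Entpd1 do not encode receptors. Pdcd1, which encodes PD-1, stood at 5.61 ± 2.68 CPM in WT and 0.82 ± 0.42 CPM in D69A tumors (SD, n = 5 each). Of 17 cytotoxic effectors, 14 were lower and Lamp1 was higher (14 and 1 adjusted over the list alone), with Ctsw 8.79-fold lower. Lamp1 encodes a lysosomal membrane protein made by most cells, and rose by 1.19-fold. The granzyme genes Gzmc and Gzmd did not pass the threshold. Scores of these 4 lists differed by -2.70 (NK), -2.56 (T cell), -2.59 (inhibitory receptors) and -2.13 (cytotoxic effectors), each with p = 0.00794 by exact permutation. None of the 4 lists was called with an estimated correlation (adjusted p = 0.213 for each).

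Genes of antigen presentation and of myeloid and B cells were lower as well. All 11 MHC class II genes fell (11 adjusted over the list alone), with H2-Ab1 6.17-fold and H2-Eb1 5.95-fold lower. Of 21 MHC class I presentation genes 20 fell (20 adjusted over the list alone), and Pdia3, a chaperone gene, did not pass the threshold. Psme2, a subunit of the proteasome activator, was 2.21-fold lower and H2-T22 2.75-fold lower, with reads that related H2 genes can share and 29.4% of its exon sequence opposite another annotated gene. Dendritic cell markers fell in 18 of 20 cases (18 adjusted over the list alone), including the migration receptor gene Ccr7 (6.85-fold lower) and the lineage transcription factor gene Irf8 (5.82-fold lower). Macrophage and monocyte markers fell in 20 of 26 cases (21 adjusted over the list alone), with the monocyte gene Ly6c2 6.31-fold and Spp1 2.57-fold lower. Neutrophil markers fell in 7 of 8 tested cases, Csf3r by 4.42-fold, and B and plasma cell markers in 6 of 7 tested cases, Ebf1 by 4.65-fold (7 and 6 adjusted over the list alone). These lists were fixed with 21 and 22 members, and most were not listed or too low in counts to be tested. Chemokine genes fell in 24 of 28 cases (24 adjusted over the list alone), with Ccl5 5.33-fold and the interferon-induced Cxcl10 3.71-fold lower. The score of each of these 7 lists differed with p = 0.00794 by exact permutation, and the camera calls of all 7 were lost with an estimated correlation (adjusted p = 0.213 for each). Some lists share members, up to 4 between the interferon-gamma and MHC class I lists.

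Genes of the IL-18 pathway other than Il18 itself were lower. Of 24 tested members 18 fell (18 adjusted over the list alone), with a median log2 fold change of -1.50. The receptor genes Il18r1 and Il18rap were 5.87-fold and 6.39-fold lower, and Il18bp, which encodes the secreted IL-18 decoy and is induced by interferon-gamma, stood at 24.8 ± 7.33 CPM in WT against 4.89 ± 2.31 CPM in D69A tumors (SD, n = 5 each). The list score differed by -1.42 (exact permutation p = 0.00794), and the camera call was lost with an estimated correlation (adjusted p = 0.213).

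Stromal genes fell too, vessel genes by less. Of 25 fibroblast and extracellular matrix genes 23 were lower and Fbln1 was higher (23 and 1 adjusted over the list alone), with a median of -2.13. The matrix genes Dcn and Postn were 6.85-fold and 4.5-fold lower, and Fbln1, which encodes a matrix glycoprotein, was 1.15-fold higher. Of 21 endothelial markers 18 were lower (18 adjusted over the list alone), with a median of -0.89, Pecam1 2.22-fold and Vwf 1.38-fold lower. Adipocyte markers fell in 7 of 9 tested cases out of 17 fixed (7 adjusted over the list alone), Fabp4 by 3.2-fold. Scores differed by -1.93, -0.92 and -1.78, with exact permutation p = 0.00794, 0.00794 and 0.0238. With an estimated correlation the 3 lists had adjusted p = 0.213, 0.213 and 0.23. Skeletal muscle markers, a sign of tissue from around the tumor, had no member past the threshold among 22 and differed widely between tumors, with the highest scores in WT tumor 4 (6.10), WT tumor 3 (5.53) and D69A tumor 1 (4.67). Their score did not differ between groups (exact permutation p = 0.262) and camera did not call the list over all 10 tumors (adjusted p = 0.0841). Leaving out WT tumor 5, WT tumor 6, D69A tumor 1 or D69A tumor 4 brought it past the threshold, with medians of -2.22, -2.27, -4.10 and -1.87. Without WT tumor 4 the median was -1.06 (adjusted p = 0.282), against -1.96 over all tumors. In these bulk tissues Tnni2 stood at 25.9 ± 30.5 CPM in WT and 5.23 ± 8.78 CPM in D69A tumors and Des at 41.6 ± 38.5 against 18.9 ± 11.6 CPM (SD, n = 5 each). Without the 3 tumors highest in muscle markers 1727 genes were higher, against 2594 with all 10, a choice made after seeing the data.

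**Figure D2:**
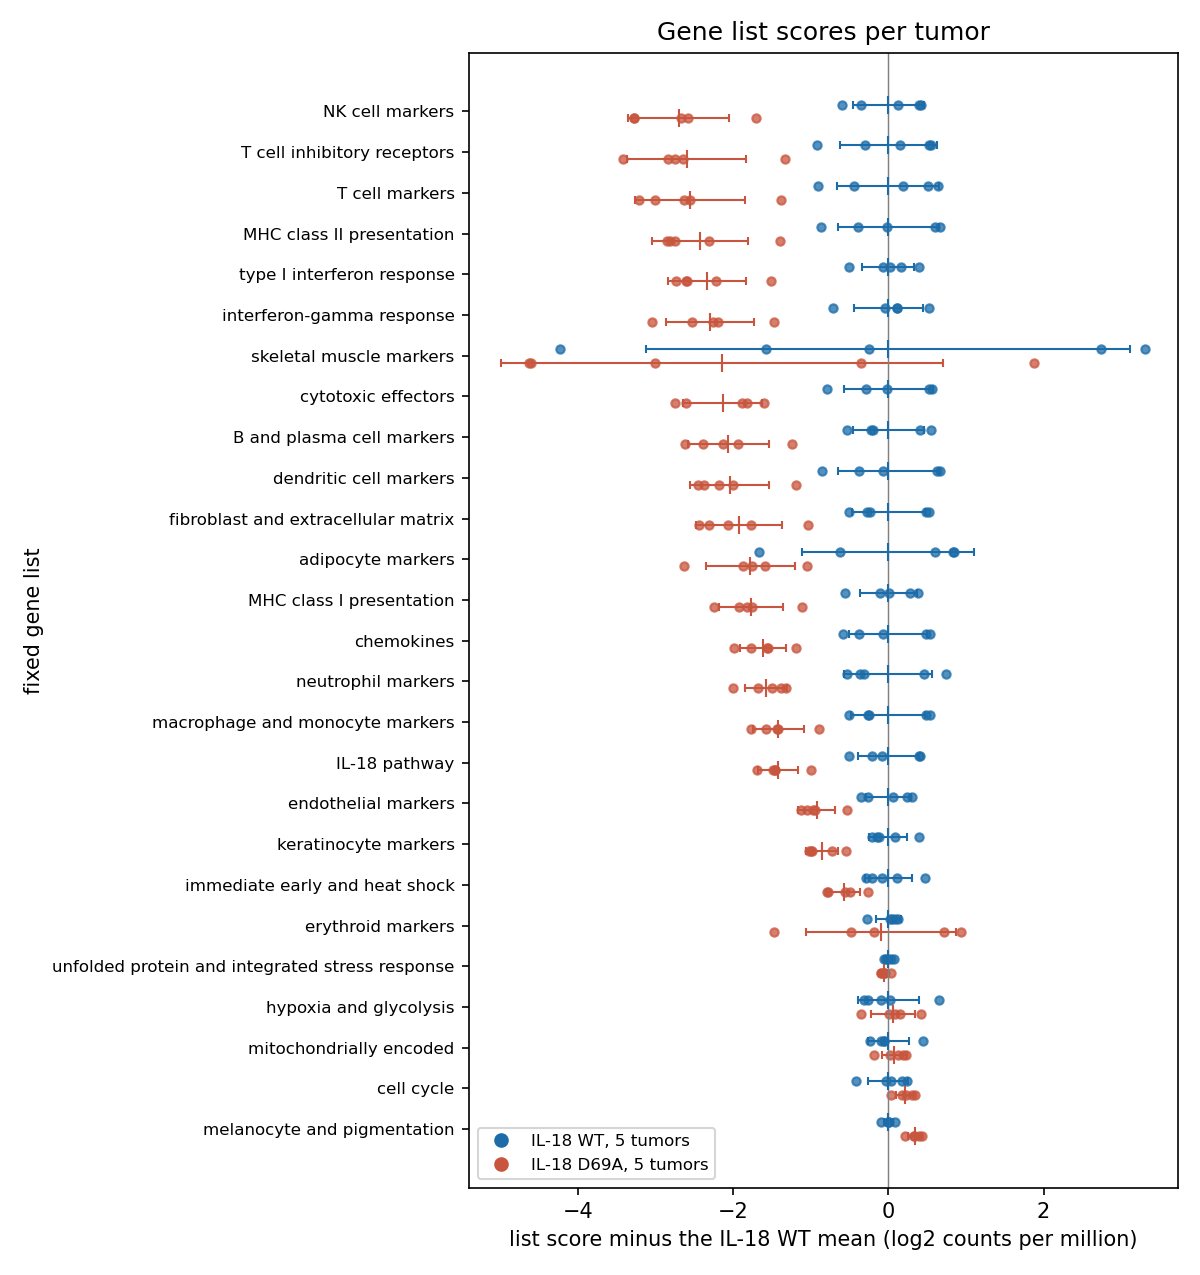
Score of each of the 26 fixed gene lists per tumor (points), as mean log2 CPM minus the mean of the WT tumors, with the group mean and SD as bars (blue WT, red D69A, n = 5 each). The NK cell list differs by -2.70, the endothelial list by -0.92 and the melanocyte list by 0.34, while the skeletal muscle list overlaps between groups.

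Pigment cell genes were modestly higher. Of 25 melanocyte and pigmentation genes 15 rose and Kit fell (16 and 2 adjusted over the list alone), with a median log2 fold change of 0.44. Mc1r, the melanocortin receptor gene, stood at 151.4 ± 6.48 CPM in WT and 204.9 ± 12.3 CPM in D69A tumors (SD, n = 5 each; log2 fold change 0.44, SE 0.05). Slc24a5, a gene of melanosome ion transport, was 1.66-fold and the receptor kinase gene Met 1.44-fold higher, whereas Kit, a receptor kinase also found on mast cells, was 2.36-fold lower. For Slc24a5, 39.5% of the exon sequence lies opposite exons of Myef2, and reads of the 2 genes are not separable unless strand was used in counting. The score rose from 8.04 ± 0.06 to 8.38 ± 0.08 (SD, n = 5 each; exact permutation p = 0.00794), and the camera call was lost with an estimated correlation (adjusted p = 0.213). Of 30 cell cycle genes 7 were higher (1 adjusted over the list alone), among them Bub1 (1.28-fold), Cenpf (1.42-fold) and Cdk1 (1.21-fold). The cell cycle list was called by camera but its score did not differ (exact permutation p = 0.135), fry did not call it, and the adjusted p was 0.57 with an estimated correlation. Cdk1 lost its call in 5 of the fits that left out 1 tumor, with an adjusted p of 0.0852 in edgeR's quasi-likelihood test without D69A tumor 4. In the same test it also lost its call with upper quartile scaling (adjusted p = 0.0795), library size only (0.112) and no low count filter (0.0678). Without the 3 tumors highest in muscle markers Cdk1 (0.143), Bub1 (0.0536) and Cenpf (0.0501) all lost their calls.

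The remaining lists moved little or in part. Immediate early and heat shock genes were lower in 8 of 19 cases (8 adjusted over the list alone), with Egr1 3.2-fold and Egr3 5.55-fold lower. Their score differed by -0.58 (exact permutation p = 0.0159), and the list had an adjusted p of 0.387 with an estimated correlation. Of 5 tested keratinocyte markers out of 21 fixed, Lgals7 and Ly6d were lower (2 adjusted over the list alone). Camera did not call this list over all 10 tumors (median -0.67, adjusted p = 0.0841), although its score differed (exact permutation p = 0.00794) and fry called it (adjusted p = 0.000451). Camera called it without WT tumor 5 (median -1.01) and without D69A tumor 2, 3, 4 or 5 (-1.20, -0.97, -1.14 and -1.06). Without D69A tumor 1 the median was -1.06 with an adjusted p of 0.0516. Of 24 hypoxia and glycolysis genes Eno1, Mif and Pgk1 were higher and Pfkfb3 lower over all genes, against 0 higher and 1 lower adjusted over the list alone. Of 20 stress response genes Atf4 was higher and Chac1 and Herpud1 lower, and of 13 mitochondrially encoded genes mt-Nd2 was higher, with 0 in either list adjusted over the list alone. None of these 3 lists was called over all 10 tumors, and their scores gave p = 0.794, 0.151 and 0.595 by exact permutation. Camera called the hypoxia list without WT tumor 5 (median 0.318, adjusted p = 0.0138, against a median of 0.081 over all tumors), and its median came to 0.000258 without WT tumor 4. The mitochondrially encoded list was called by camera without WT tumor 4 (median 0.23, adjusted p = 0.0341) and without the 3 tumors highest in muscle markers (median 0.29, adjusted p = 0.0053). Eno1, Mif, Pgk1, Chac1, Herpud1 and mt-Nd2 each lost the call when at least 2 single tumors were left out in turn, with adjusted p up to 0.0902 (Pgk1 without WT tumor 4, edgeR's quasi-likelihood test). No erythroid marker of 6 tested out of 12 fixed passed the threshold, and Hbb-bs stood at 52.6 ± 9.19 CPM in WT and 68.0 ± 47.5 CPM in D69A tumors (SD, n = 5 each; exact permutation p = 0.905 for the score). The median log2 fold change of the erythroid list was 0.27 and its score difference -0.10, opposite in sign. The median went from -0.10 without D69A tumor 5 to 0.53 without D69A tumor 1, which had the lowest score (1.87, against 2.86 to 4.27 in the other D69A tumors).

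Among the genes that the naming rule admits (mean of at least 1 CPM), Tex13b had the largest fitted decrease. This testis-expressed gene on chromosome X (140808307 to 140813433 in mm10) went from 18.9 ± 4.65 CPM in WT to 0.97 ± 0.10 CPM in D69A tumors (SD, n = 5 each). Its log2 fold change was -4.28 (SE 0.20, adjusted p = 3.25e-06 in edgeR's quasi-likelihood test). No label states whether each implanted line was 1 clone or a pool. A difference between the lines is thus not told apart from the substitution, here or for the increases below. Ptprcap, which encodes a partner of the leukocyte phosphatase CD45, was 18.1-fold lower, with 76.0% of its exon sequence opposite exons of Rps6kb2 and 26.8% shared with Coro1b on the same strand. The nuclease gene Dnase1l3 was 15.1-fold lower, the scavenger receptor gene Scara5 13.9-fold, and the interferon-induced Serpina3g had a log2 fold change of -3.59. With 1 tumor left out in turn, the log2 fold change ranged from -4.95 to -3.53 for Dnase1l3 and from -4.2 to -3.02 for Scara5. Cyp2e1 was 12.5-fold lower (adjusted p = 0.0271) and lost its call in 4 of the fits that left out 1 tumor, up to an adjusted p of 0.062 in edgeR's quasi-likelihood test without WT tumor 3. The call was also lost with limma-voom (adjusted p = 0.172) and with limma-voom with sample weights (adjusted p = 0.242).

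Of the genes with the largest increases that the naming rule admits, several were low in both groups, whereas Igfn1, Syt4 and Fndc3c1 were not. Mov10l1, a helicase gene of the germline piRNA pathway, rose from 0.16 ± 0.11 to 3.85 ± 1.98 CPM (SD, n = 5 each; log2 fold change 4.51, SE 0.58, adjusted p = 0.000517 in edgeR's quasi-likelihood test). Igfn1 was 4.85-fold higher (102.5 ± 33.8 CPM in WT against 497.7 ± 98.4 CPM in D69A tumors). The vesicle protein gene Syt4 was 3.79-fold higher (27.9 ± 3.68 against 105.9 ± 16.6 CPM), Fndc3c1 3.26-fold and Capn6 3.99-fold. The granzyme gene Gzmg passed narrowly (log2 fold change 3.75, SE 1.39, adjusted p = 0.048 in edgeR's quasi-likelihood test) and was highest in D69A tumor 2 (9.38 CPM). The call was lost in 7 of the 10 fits that left out 1 tumor: without each WT tumor (adjusted p = 0.0507, 0.0627, 0.0969, 0.0777 and 0.0862 for WT tumors 2 to 6), without D69A tumor 2 (log2 fold change 2.05, adjusted p = 0.211) and without D69A tumor 4 (0.0728). It was also lost with DESeq2 (adjusted p = 0.0656) and limma-voom (adjusted p = 0.293), and reads can be shared among neighboring granzyme genes.

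**Figure D3:**
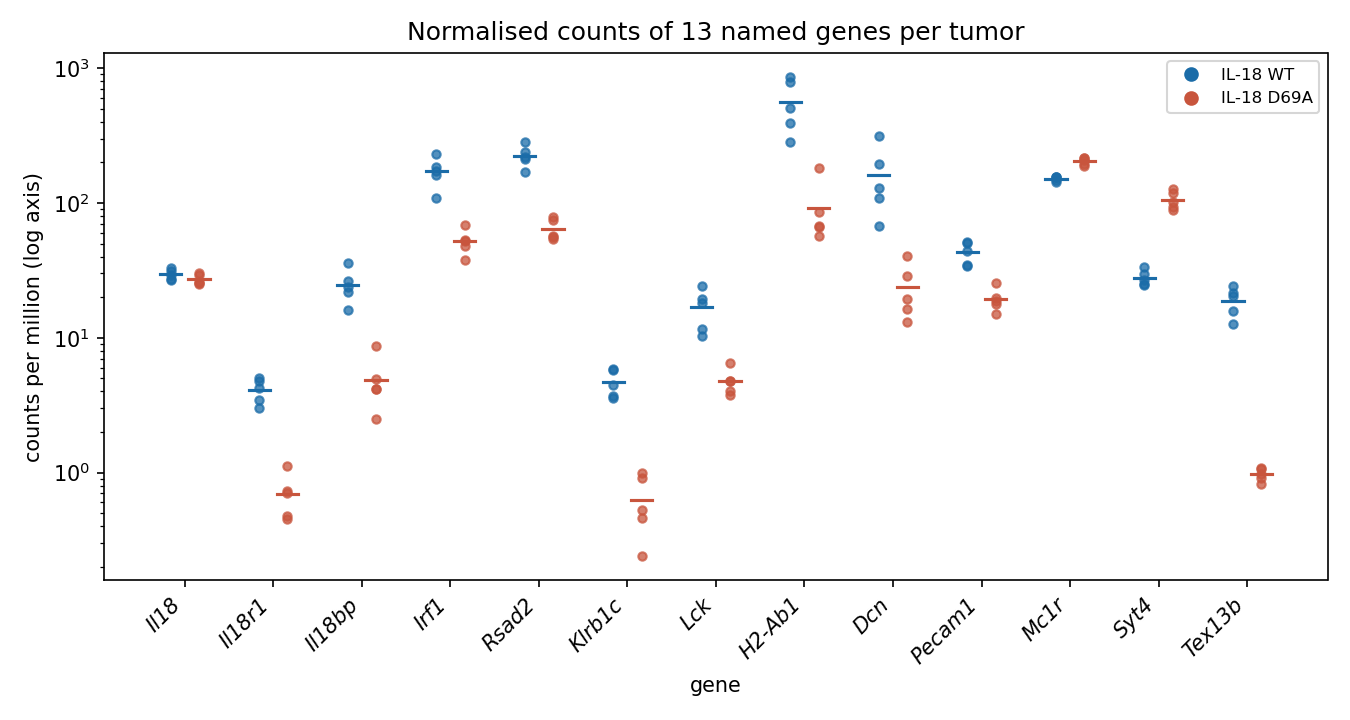
CPM of 13 genes in each tumor on a log axis, blue for WT and red for D69A, with a horizontal bar at each group mean (n = 5 each). Il18 overlaps between groups, the immune and stromal genes are lower in D69A tumors, and Mc1r and Syt4 are higher.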

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

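A tumor was singled out when its gap to the nearest tumor of its group was large relative to the range of the group. Of 216 groups of values examined, 18 (8.33%) met this, and 12 of them were in D69A tumors. Chance gives about 1 in 20 for independent, normally distributed values. CPM need not be normal and values of a tumor vary together, so the share does not show an excess. The tests of exchanged labels and mixing were chosen after the results were seen.

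D69A tumor 1 was above the rest of its group in immune genes, in muscle genes and in vessel markers. It held 3.88 CPM of Socs1 (others 1.74 to 2.12), 182 CPM of H2-Ab1 (57.0 to 85.3), 179 CPM of H2-Eb1 (55.1 to 75.1), 1.55 CPM of Pdcd1 (0.541 to 0.799), 12.2 CPM of Ccl5 (5.71 to 6.38), 59.0 CPM of Irf8 (21.6 to 28.8) and 4.41 CPM of Dnase1l3 (0.18 to 1.01). Its muscle genes Tnni2 (20.7 CPM, others 0.353 to 3.93) and Des (39.3 CPM, others 12.5 to 17.4) and its endothelial list score (3.39, others 2.79 to 2.97) were also high.

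WT tumor 2 and D69A tumor 1 lay between the groups on the first principal component, which raised the question of exchanged labels or mixed material. Exchanging the 2 labels gave 3285 genes past the threshold against 6004 with the labels as given, where an exchange would have raised the count. Over genes at least 2-fold apart without the 2 tumors, the median share of the other group in WT tumor 2 was 60.4% by 2405 lower and 28.3% by 124 higher genes, and in D69A tumor 1 20.4% and 43.6%. Mixing alone would give equal shares by both sets, but the gaps, 32.1 and 23.2 percentage points, lay within those of the other 8 tumors (0.2 to 36.3; up to 16.7 in the other D69A tumors) and decide nothing. A mixed tumor also holds at least the share times the lowest level in the other group. At the lower quartile of the share by lower genes, 47.4% in WT tumor 2, 4 of 17 genes able to show it lay below that level by more than counting error (binomial p = 0.000716): Mov10l1 with 0.129 CPM (D69A tumors 1.84 to 6.80), Syt4 with 29.6 CPM (88.6 to 127), Igfn1 with 137 CPM (379 to 601) and Syce1 with 0.31 CPM (1.30 to 2.37). This argues against a share of 47.4% in WT tumor 2, with the spread between tumors left out of the test. Shares by lower genes differ between tumors, with a median of 48.1% in WT tumor 6, so mixing at a smaller share stays open. In D69A tumor 1, at 13%, 1 of 24 genes did (binomial p = 0.455), Tex13b with 0.829 CPM (WT tumors 12.6 to 24.4), so mixing of WT material into D69A tumor 1 stays open. An earlier test took genes at least 2-fold apart at an equal interferon score in the 8 tumors other than these 2. It found 0 such genes and so decided nothing. A weaker or stronger immune response of these single tumors stays open and was not tested.

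Other single tumors stood apart in 1 or 2 values each. D69A tumor 2 held 9.38 CPM of Gzmg (others 0 to 2.22) and 9.88 CPM of Gzmd (others 0.107 to 2.4). WT tumor 5 held 2560 CPM of Pgk1 (others 1550 to 1820) and 42.5 CPM of Scara5 (others 5.81 to 14.6). WT tumor 4 had the highest mitochondrial share of counts, 3.54% (others 2.44 to 2.64), and a mitochondrially encoded list score of 10.4 (others 9.67 to 9.86). Among the WT tumors, tumor 3 had the lowest erythroid list score, 3.06 (others 3.36 to 3.47), and tumor 6 the lowest total, 25.9 M counts (others 36.4 to 37.6 M).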

How the results depend on the processing

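The analysis without the 3 tumors highest in muscle markers was chosen after the data were seen. Signs were compared for the named genes and the lists only, and most of these genes were chosen for a small p or a large change. Among them no value past the threshold changed sign under any setting in which it was computed. The medians of 2 lists that were not called did: erythroid (0.27, and -0.10 without D69A tumor 5) and stress response (-0.0235, and 0.0406 without D69A tumor 3; it was also above 0 without WT tumor 2 or WT tumor 5). The count of genes past the threshold stayed within 1.5 times of 6004 except at a stricter criterion: 1860 genes (60 higher, 1800 lower) when tested against a fold of 1.5, and 3651 (1334 higher) at an adjusted p of 0.01, as both ask more of a gene. Without the 3 muscle-high tumors 4342 genes passed, 4181 of them shared with the full set, and 1727 were higher; the cause of the drop beyond fewer samples was not tested. Leaving out single tumors gave 4966 (without WT tumor 3) to 6460 genes (without D69A tumor 1), with 2095 to 2936 higher and 2826 to 3631 lower, 20 to 23 lists by camera and 19 to 21 by score, and Il18 at -0.14 to -0.07. The lists had medians of -2.51 to -2.09 (interferon-gamma), -2.69 to -2.23 (type I), -3.10 to -2.61 (NK) and -3.14 to -2.43 (T cell). With an estimated correlation 0 of 26 lists were called by camera (smallest unadjusted p = 0.0694, so 0 lists under an unadjusted 0.05), against 20 by fry and 20 by permutation of scores; the interferon-gamma (-2.28), type I (-2.37), NK (-2.74) and T cell (-2.65) lists all had an adjusted p of 0.213. Leaving out 1 tumor added 11 list calls by camera, in the keratinocyte, skeletal muscle, mitochondrially encoded and hypoxia lists. The share of calls that were lower was 56.8% with TMM and 66.4% by library size only. Of 1765 values of named genes under these settings, 116 changed their side of the threshold. Replicate numbers did not pair the tumors: the 4 same-number pairs had correlations of deviations from -0.42 to 0.20, and 1 WT tumor correlated best with its own number. The replicate block gave 5464 genes, 5028 shared with the fit without it, and 21 lists. WT tumor 6 and D69A tumor 1 had no partner of the same number, so under the block they did not bear on the group difference. Their muscle list scores were -1.44 and 4.67, and leaving out either alone also brought that list past the threshold. Under the block the skeletal muscle list (median -4.61, camera adjusted p = 4.28e-07), Tnni2 (adjusted p = 0.00263) and Des (0.0415) gained calls, and Mif (0.081) and Atf4 (0.0514) lost theirs in edgeR's quasi-likelihood test. These changes are not told apart from the loss of the unpaired tumors. On simulated data with 200 changed genes, 6% were recovered at the smallest simulated change. In the real fit 43.5% of the genes passed, which makes the adjusted threshold less strict, so this share does not carry over.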

Other observations

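Lipid synthesis and complement genes also differed between the groups. These lists and the tests of muscle tissue, melanoma share and sterol genes were chosen after the results were seen; the splits and the interferon covariate were planned before. Of 24 sterol synthesis genes 22 were higher in D69A tumors, with a median log2 fold change of 0.74. Sqle, which encodes squalene epoxidase, was 1.78-fold higher. All 9 fatty acid synthesis genes were higher, with Fasn 1.83-fold and Scd1 2.17-fold. Of 14 complement genes 13 were lower, with C3 6.13-fold, C4b 5.41-fold and the inhibitor gene Serping1 6.81-fold lower. List scores differed by 0.75, 0.77 and -1.96, with exact permutation p = 0.0159, 0.00794 and 0.00794, and camera with an estimated correlation gave unadjusted p = 0.189, 0.0942 and 0.112. Because these lists were chosen after the results were seen, the p-values give no independent support.

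The number of genes past the threshold was set against other splits of the 10 tumors into 5 and 5. Of 100 splits drawn with a fixed seed, the real one included, 1 gave as many as 6004 genes, and the highest of the others gave 3285. Chance is thus unlikely to give the gene count, though 1 of 100 is the smallest share these splits allow. They do not bear on a difference between the implanted cell lines. For the number of lists called by camera chance cannot be excluded: 35 of the 100 splits gave as many as 20, and the highest of the others gave 22. The members of a list vary together from tumor to tumor, with an estimated correlation of 0.845 in the type I interferon list against the preset 0.01. The exact permutation test of each score assumes no such value.

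Host cell lists were lower in D69A tumors, which a larger share of melanoma cells could bring about. The melanocyte list score was 0.34 higher in D69A tumors (exact permutation p = 0.00794), the direction that such a share would give. If melanoma cells expressed none of the list members, a uniformly larger share would lower every host list alike. Yet of 21 pairs of 7 host lists 16 differed in how far their scores fell (exact permutation with Benjamini-Hochberg adjustment over the pairs). The NK score fell further than the endothelial score, with a per-tumor difference of -1.78 (adjusted p = 0.0167), while the other 5 pairs did not pass, among them NK and T cells (-0.142, adjusted p = 0.25), dendritic cells and fibroblasts (-0.114, adjusted p = 0.532) and T cells and fibroblasts (-0.633, adjusted p = 0.0686). This argues against a uniform share as the whole cause only if melanoma cells express none of the list members, which was not tested. The NK score also fell further than the erythroid score (-2.6, adjusted p = 0.0357 by exact permutation). The macrophage and endothelial scores did not pass against it (adjusted p = 0.0926 and 0.184). Within the endothelial list itself Vwf was 1.38-fold and Pecam1 2.22-fold lower, unequal falls that a uniform share alone would not give under the same condition. As that condition was not tested, a uniform share is not excluded. Muscle tissue collected with some tumors is argued against as the whole cause, since the NK list had a median of -2.94 without the 3 muscle-high tumors. A smaller share of certain host cells, a lower expression per cell, and a difference between the implanted cell lines other than the form of IL-18 stay open, and bulk RNA does not separate the first pair.

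The hypothesis that the other differences follow the interferon response was tested by adding the interferon-gamma score as a covariate. It left 1 gene past the threshold, Tex13b. This decides nothing, since the score has a correlation of -0.93 with the group: when it was shuffled within each group in 20 draws, a median of 0 genes and at most 569 passed. The median SE of the 6004 genes grew from 0.13 to 0.30 and their median absolute log2 fold change went from 0.57 to 0.21. Because the covariate and the group cannot be told apart here, which genes differ apart from interferon remains open.

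A candidate explanation of the higher sterol genes is a larger share of melanoma cells. The median log2 fold change of the sterol list, 0.736, lay within the range of the 25 melanocyte genes (-1.24 to 1.35, upper quartile 0.652), and the list was picked because its genes were high, so the values decide nothing about that share. A change of lipid synthesis within melanoma or host cells stays open as well.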
